A study of Mus musculus with 24 samples.

How the data were processed

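Messenger RNA of 24 mouse libraries had been sequenced, 18 from wounds of diabetic mice (control and hydrogel at days 1, 7 and 14, n = 3 each) and 6 from RAW264.7 cells (without and with hydrogel, n = 3 each). The values analysed were counts of read pairs per gene symbol as the authors deposited them. Per the submitters' processing notes, reads were trimmed with Trim Galore 0.6.10, checked with FastQC 0.11.9, aligned to mm10 with HISAT2 2.2.1, sorted with SAMtools 1.9 and counted with featureCounts 2.0.6. Per the file headers the authors made the counts over exons by gene name from the GENCODE M25 annotation, with read pairs as the unit and without use of strand. Pairs that mapped to several places or to several genes were not counted, loci of the same name were merged, and antisense transcripts cannot be told from sense. The filter behind the high-quality alignments that were counted is not stated. The files held 52976 gene symbols, and the 32 mitochondrial symbols stood at 0 in every library, so mitochondrially encoded transcripts were not analysed here. Raw reads were not used here.

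Samples were grouped by their titles. Total counts were 12.4 M to 27.1 M per wound library and 17.9 M to 24 M per cell library. Groups, comparisons, gene lists, naming rules and all alternatives except 3 were fixed before the data were examined. Those 3 were chosen after the data had been seen: day 7 libraries summed within each group, 2 control libraries left out, and scores of skeletal muscle and adipocyte genes as covariates. Analyses were run in R 4.3.3. Genes were kept with filterByExpr of edgeR 4.0.16 (minimum count 10, minimum total 15), which left 17592 genes in wounds and 12972 in cells. Library sizes were scaled by TMM. The edgeR quasi-likelihood F test with robust dispersion was fitted to all 18 wound libraries with 6 group means (12 residual degrees of freedom) and separately to the 6 cell libraries (4 residual degrees of freedom). Genes passed at a Benjamini-Hochberg adjusted p below 0.05. Hydrogel was compared with control at each day, averaged over the 3 days and between days by an interaction test. Days 7 and 14 were compared with day 1 within each arm. The words rose and fell are used of genes that passed.

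From 53 lists written from general knowledge, 846 of 852 symbols were in the files, and lists with at least 3 tested members were tested with camera of limma 3.58.1 at a preset correlation of 0.01, with Benjamini-Hochberg adjustment over lists. The correlation between list members was also estimated from the data, and the fry test was run. An adjustment over the list alone uses the p-values of that list's members. Log2 fold changes are edgeR estimates with standard errors, and levels are CPM (counts scaled to library size and TMM) as mean and SD, with a prior count of 2 where logarithms were averaged. Where a group had no counts, a fold was bounded with a floor of 3 counts over the group, and with 1 to 3 counts the ratio is given with an exact 95% counting interval. Such bounds and intervals cover counting error only.

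Genes were named by rule: up to 10 per direction by size of change for hydrogel comparisons and 5 for others, among genes that passed, had a mean of at least 5 CPM in the higher group and whose groups did not overlap (for the average, the same sign at each day), predicted or clone-based symbols left out; up to 4 members by adjusted p of lists with at least 2 members past; up to 10 genes by adjusted p for the interaction; and a panel of 18 genes given in every hydrogel comparison. The text gives them in that order and may stop early. Alternatives were RLE size factors, no filter or a stricter filter on low counts, a 2-fold minimum, DESeq2 1.42.0, limma-voom with quality weights, only the compared groups in the model, replicate number as a block, each library left out in turn, and the 3 alternatives named above. The tests were tried on simulated counts with known changes, with the same spread in every group and with each group's own spread. Each simulation was 1 draw with 200 changed genes and 1 raised list, and a group's own spread was 1 value for all its genes. The shares of unchanged genes below hold for that setting and are not estimates for the real calls. With the same spread, 4-fold changes were found in 58% of genes at day 1, 66% at day 7, 67% at day 14 and 100% in cells, and 2-fold changes in 5%, 5%, 7% and 96%. Of the genes called, 1.19% to 6.41% had not been changed. With each group's own spread, unchanged genes made up 57.8% of the calls at day 1, 0% at day 7, 8.45% at day 14, 5.11% for the average, 80% for the interaction (4 of 5 calls) and 0.446% in cells. Coordinates are those in the files (GRCm38).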

Results

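Messenger RNA was sequenced from 24 mouse libraries, 18 from wounds of diabetic mice and 6 from RAW264.7 cells, an established mouse macrophage line. The series concerns a peptide hydrogel that carries silver nanoclusters and an oxygen-tolerant hydrogenase, an enzyme that forms molecular hydrogen, and that is meant to release hydrogen under light in diabetic wounds. The wound libraries fell into 6 groups of 3: diabetic control and hydrogel wounds at days 1, 7 and 14. The RAW264.7 libraries fell into 2 groups of 3, without and with hydrogel. Samples were grouped by their titles. The titles name control and treated wounds Dia and TEOA, and the cells Without_H2 and H2. No title names the hydrogel, which the labels name, and the titles name treated wounds and treated cells differently. The label of the RAW264.7 controls names lipopolysaccharide (LPS), a bacterial component that activates macrophages, and the label of the hydrogel-treated cells names the gel and not LPS, while the series design describes LPS-induced macrophages in both arms. The labels do not settle this. If the hydrogel-treated cells had received no LPS, each difference between the cell groups would include the LPS itself. Several genes that LPS induces, chosen after their values were seen, stood at like levels in both groups: Csf3 at 3846 to 4504 CPM (counts scaled to library size) with hydrogel and 3723 to 3768 CPM without, Cxcl2 at 6899 to 8472 and 7756 to 8010 CPM, Ccl3 at 13550 to 13910 and 13000 to 13230 CPM and Tnf at 2698 to 2781 and 3108 to 3263 CPM. Others were lower with hydrogel, such as Il1b at 98.65 to 137.1 against 423.6 to 438.1 CPM. No library of unstimulated cells was there for comparison. The labels of the 3 hydrogel-treated cell libraries also carry 3 different gel suffixes, and those of the 9 hydrogel wound libraries carry a single suffix.

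Total counts per library ran from 12.4 M to 27.1 M in the wounds and from 17.9 M to 24 M in the cells, and 20683 to 24522 gene symbols per wound library had at least 1 count. Nothing in the labels said that replicates came from separate animals or cultures. The p-values therefore measure only the spread between these libraries, which may be technical. That spread was uneven. The coefficient of variation within a group was 54.7% in control wounds at day 1, 4.68% at day 7 and 51.8% at day 14, and 43.3%, 11% and 15.3% in hydrogel wounds at the same days. RAW264.7 controls differed by 1.76% and hydrogel-treated cells by 10.3%. Summed over genes, counts differed by more than sampling noise between every pair of replicates, but the median chi-square per gene was 0.503 to 0.627 between RAW264.7 controls, where sampling noise alone gives 0.455. Between day 7 control wounds it was also low, at 0.646 to 0.816, against 9.06 to 47.5 between control wounds of day 1 or of day 14. Each library was taken as 1 sample by its title.

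Some libraries stood apart from others of their group. Control day 1 replicate 1 had a mean log2 CPM of 6.18 over the skeletal muscle list, against 10.75 and 10.96 in the other 2 day 1 controls, and of 10.20 over the adipocyte list, against 8.33 and 7.40. Fabp4, the fatty acid carrier of adipocytes, stood at 40620 CPM there and at 6881 and 3118 CPM in the others. Control day 14 replicate 1 held little epidermis-type RNA: Krt14, a keratin of basal keratinocytes, stood at 151.7 CPM against 1613 and 2139 CPM in the other day 14 controls, and the basal keratinocyte list at 4.77 against 7.06 and 7.37. Its collagen list mean was 9.64 against 8.96 and 8.11, and its macrophage list mean 6.52 against 4.94 and 3.94. Hydrogel day 1 replicate 1 stood apart too, with a coefficient of variation of 0.508 and 0.444 from the other 2 libraries of its group, against 0.294 between those. On the second principal component it lay at -14 and they at -108 and -80.3. The first principal component of the wound libraries held 40.5% of the variance and the second 23.5%.

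**Figure D1:**
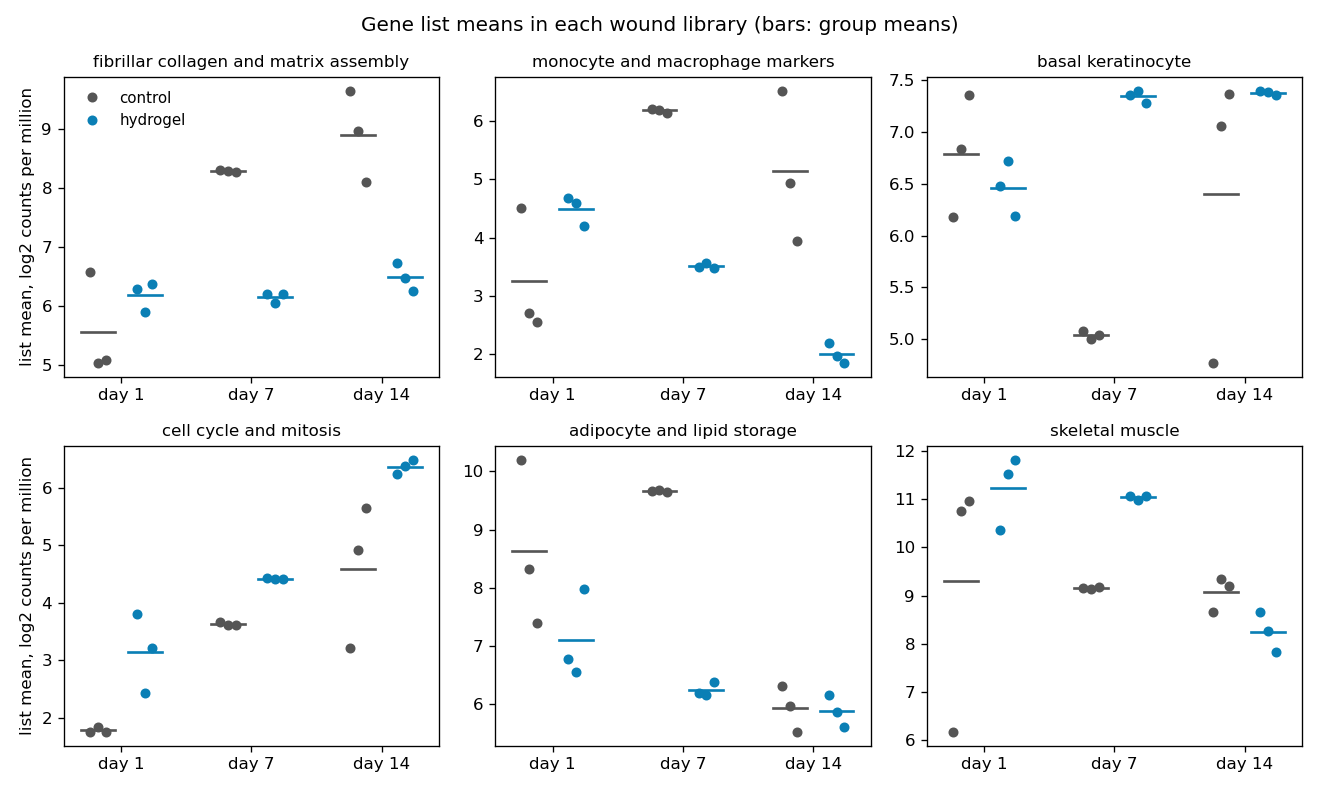
Mean log2 CPM of the members of 6 fixed gene lists in each of the 18 wound libraries, by day, with each library as a point, control in grey and hydrogel in blue, and bars at the group means. Day 7 replicates lie close together, and control day 14 replicate 1 lies apart from the other 2 controls of its day in the collagen, macrophage and keratinocyte lists.

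At day 1, hydrogel wounds (n = 3) were set against control wounds (n = 3) to describe the early wound. Saa3, an acute-phase serum amyloid gene (chromosome 7, 46711998 to 46715700, minus strand, GRCm38), stood at 1111 ± 390.1 CPM (mean ± SD) against 33.3 ± 25.7, a log2 fold change of 5.06 ± 1.19 (SE; adjusted p = 0.0224). Rrad, a small GTPase-like gene of muscle, rose by a log2 fold change of 4.70 ± 0.94 (adjusted p = 0.0112), and Fbxl22, an F-box gene of muscle, by 4.45 ± 0.79. Mefv, which encodes pyrin, rose by 4.20 ± 0.57 on that scale, from 0.268 ± 0.200 to 5.12 ± 2.00 CPM, and Serpinb1a, an inhibitor of neutrophil serine proteases, by 4.17 ± 0.43 (adjusted p = 0.00032), from 4.05 ± 1.69 to 73.1 ± 26.9 CPM. Among lower genes, Ucp1, the uncoupling protein of thermogenic fat, had a log2 fold change of -7.04 ± 1.38 (adjusted p = 0.0104), at 0.554 ± 0.344 against 76.9 ± 96.3 CPM, with 185.3 CPM in control day 1 replicate 1 alone, and did not pass with limma-voom weights or with muscle and adipocyte scores as covariates. Irf4 followed at -4.83 ± 0.91, also highest in that library at 186.4 CPM, and Calcb, a neuropeptide gene, at -4.55 ± 0.92.

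Of 27 tested cell cycle genes, 10 rose and 0 fell at day 1, or 20 rose when adjusted over the list alone, with a median log2 fold change of 1.595 (camera adjusted p = 4.28e-10; adjusted p = 0.794 with an estimated correlation). Birc5, which encodes survivin, rose by 2.58 ± 0.52 on the log2 scale. Neutrophil markers rose in 6 of 17 cases and fell in 0, or 8 rose adjusted over the list alone, with a median of 2.04 (adjusted p = 0.00166; adjusted p = 0.794 with an estimated correlation), among them Csf3r, the receptor of granulocyte colony-stimulating factor, at 3.42 ± 0.68. Of 19 macrophage markers, 3 rose and 16 did not pass, or 4 rose adjusted over the list alone (median 0.48, adjusted p = 0.0235; adjusted p = 0.855 with an estimated correlation), led by the Fc receptor gene Fcgr1 at 3.06 ± 0.63 and the chemokine receptor gene Ccr2 at 3.28 ± 0.72. Adipocyte genes fell in 4 of 19 cases, or 13 adjusted over the list alone, with a median of -2.12 (adjusted p = 4.93e-06; adjusted p = 0.794 with an estimated correlation). Skeletal muscle genes moved upward as a list (median 0.74, adjusted p = 0.00166; adjusted p = 0.855 with an estimated correlation), while 0 of 26 passed singly, also when adjusted over the list alone. The list did not pass without control day 1 replicate 1 (adjusted p = 0.838). The adipocyte and muscle markers were those in which that library stood apart. Of 9 erythrocyte genes, 5 fell, or 6 adjusted over the list alone, with a median of -2.89 (adjusted p = 1.09e-05; adjusted p = 0.794 with an estimated correlation). Hba-a1 had a log2 fold change of -2.99 ± 0.54, uncertain because near-identical haemoglobin copies share reads, and Alas2, the haem synthesis enzyme of red cells, of -2.84 ± 0.53. T and NK cell markers fell in 3 of 20 cases, or 4 adjusted over the list alone (median -1.01, adjusted p = 0.00695; adjusted p = 0.794 with an estimated correlation), with Cd3e, a T cell receptor subunit, at -2.99 ± 0.56.

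In all, 1329 of 17592 genes passed at day 1, 797 higher and 532 lower, and 4563 had an unadjusted p below 0.05. Groups did not overlap in 17.1% of genes, where chance gives 10% for 3 against 3 if the libraries are separate samples. The count depended on the processing. With only the 2 groups compared in the model, edgeR called 0 genes (1701 at an unadjusted p below 0.05), and with the day 7 libraries of each group summed it called 14 (3245 unadjusted), while DESeq2 called 2626 and limma-voom with quality weights 4345. In data simulated with each group's own spread, 57.8% of the genes called at day 1 had not been changed (118 genes, in a simulation with 200 changed genes). That share depends on how many genes were changed and is not an estimate for the 1329 real calls. The count was 753 without control day 1 replicate 2, 3012 without hydrogel day 1 replicate 1, 809 without hydrogel day 1 replicate 2 and 425 without hydrogel day 1 replicate 3. Saa3 lost its call without control day 1 replicate 2 (adjusted p = 0.0711) or replicate 3 (adjusted p = 0.0528), within a range of 1.79e-05 to 0.294 over all alternatives. Lists passed in 15 of 44 cases, 8 up and 7 down, and in 5 without hydrogel day 1 replicate 1. Without that library the neutrophil list had an adjusted p of 0.0599, the macrophage list of 0.251 and the T and NK list of 0.0599. The macrophage list also lost its call without control replicate 2 (median 0.24, adjusted p = 0.153) or 3 (0.09, 0.23), but without control replicate 1 its median was 2.10 (1.46e-07) and with the muscle and adipocyte covariates 2.62 (3.03e-09). The T and NK list lost its call without control replicate 3 (median -0.67, adjusted p = 0.109). The neutrophil median was 0.91 without hydrogel replicate 2 (0.0178), the adipocyte median -0.44 without control replicate 1 (0.0096) and the erythrocyte median -1.79 without control replicate 2 (0.000364). The muscle median was 0.18 without control replicate 1, 1.25 without control replicate 2, 1.14 without hydrogel replicate 1 and 0.46 without hydrogel replicate 3. With limma-voom weights the adipocyte list stood at 0.336 and the neutrophil list at 0.41. An estimated correlation left 0 of 44 lists past (1 at an unadjusted p below 0.05), and the fry test also 0 (10 unadjusted).

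At day 7, keratin genes of basal keratinocytes were much higher in hydrogel wounds (n = 3) than in control wounds (n = 3). Krt14 (chromosome 11, 100203162 to 100207548, minus strand, GRCm38) stood at 3048 ± 51.7 against 117 ± 3.03 CPM, a log2 fold change of 4.71 ± 0.68 (adjusted p = 0.0012), and Krt5, its partner keratin, at 2859 ± 52.4 against 200.6 ± 3.04 CPM. Collagen genes were lower. Col1a1, a chain of type I collagen (chromosome 11, 94936224 to 94953042, plus strand), stood at 359.3 ± 33.8 against 2322 ± 40.5 CPM, a log2 fold change of -2.69 ± 0.39 (adjusted p = 0.00128), and Col3a1 at 549.3 ± 36.01 against 5422 ± 46.2 CPM (-3.30 ± 0.69, adjusted p = 0.00521). Lep, the adipocyte hormone leptin (chromosome 6, 29060220 to 29073877, plus strand), fell by 6.01 on the log2 scale (SE 0.58, adjusted p = 0.000187), from 27.4 ± 1.36 to 0.411 ± 0.201 CPM.

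Several of the genes with the largest changes at day 7 had hardly any counts in one arm. Atp6v1b1, a proton pump subunit, stood at 6.46 ± 0.38 CPM with hydrogel and at 0 in all 3 controls, at least 91.6-fold higher against a floor of 3 counts over the group. Ugt1a1 was 726-fold higher (95% counting interval 130 to 28700) and Cyp3a57 442-fold higher (151 to 2140). Both belong to families whose members share sequence, so the values of Ugt1a1, Cyp3a57 and the steroid dehydrogenase Hsd3b6 (100.4 ± 6.77 against 0.184 ± 0.175 CPM) are uncertain between family members. Hsd17b2, another steroid dehydrogenase, stood at 27.0 ± 1.03 against 0.0961 ± 0.0834 CPM. Tyr, the tyrosinase of melanocytes, was 230-fold higher (63.6 to 1900). In the other direction, Gsc was 428-fold lower (76.8 to 16900) and Igsf21 192-fold lower (53.1 to 1580). Angptl8, a hormone of fat and liver, stood at 0.227 ± 0.099 against 28.6 ± 0.76 CPM. These intervals cover counting error only.

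By lists, collagen and matrix assembly genes fell in 21 of 24 cases at day 7, or 23 adjusted over the list alone, with a median of -2.11 (adjusted p = 1.95e-13; adjusted p = 0.271 with an estimated correlation). Lum, the small proteoglycan lumican, had a log2 fold change of -2.57 ± 0.46 and Loxl2, which cross-links collagen, of -1.74 ± 0.31. Macrophage markers fell in 18 of 19 cases, or 19 adjusted over the list alone, with a median of -2.86 (adjusted p = 1.09e-10; adjusted p = 0.282 with an estimated correlation). Cd68 stood at -2.25 ± 0.43, Tyrobp, a myeloid signalling adaptor, at -3.09 ± 0.65 and Csf1r, the macrophage growth factor receptor, at -2.55 ± 0.54. Endothelial genes fell in 17 of 23 cases, or 19 adjusted over the list alone (median -1.63, adjusted p = 5.46e-09; adjusted p = 0.282 with an estimated correlation), with the junction gene Cldn5 at -2.89 ± 0.44 and the VEGF receptor Kdr at -2.44 ± 0.39. Fibroblast markers fell in 9 of 19 cases, also adjusted over the list alone (median -1.24, adjusted p = 1.9e-05; adjusted p = 0.271 with an estimated correlation), led by Lrrc15 at -3.18 ± 0.30. Of 19 interferon response genes 8 fell, or 17 adjusted over the list alone (median -1.97, adjusted p = 2.4e-06; adjusted p = 0.341 with an estimated correlation), with Oasl1 at -2.996 ± 0.709 and Irf7, a master regulator of that response, at -3.62 ± 0.89. Adipocyte genes fell in 15 of 19 cases with a median of -4.11 (adjusted p = 2.3e-12; adjusted p = 0.271 with an estimated correlation), or in 16 adjusted over the list alone, where 1 rose.

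Basal keratinocyte genes rose in 11 of 15 cases at day 7, or 13 adjusted over the list alone, with a median of 2.29 (adjusted p = 5.46e-09; adjusted p = 0.271 with an estimated correlation). Epidermal differentiation genes rose in 12 of 23 cases, or 19 adjusted over the list alone (adjusted p = 3.6e-09; adjusted p = 0.282 with an estimated correlation). Casp14, a protease of the cornifying layer, had a log2 fold change of 4.85 ± 0.72 and Sbsn, suprabasin, of 3.25 ± 0.52. Wound-edge keratinocyte genes rose in 9 of 20 cases, or 12 adjusted over the list alone (median 2.94, adjusted p = 1.85e-06; adjusted p = 0.306 with an estimated correlation). Cholesterol synthesis genes rose in 14 of 19 cases and 1 fell (median 2.42, adjusted p = 1.42e-07; adjusted p = 0.282 with an estimated correlation), also when adjusted over the list alone. Sqle, squalene epoxidase, rose by 4.26 ± 0.67 and Mvd by 2.58 ± 0.44 on the log2 scale. Glycolysis genes rose in 9 of 19 cases, or 10 adjusted over the list alone (median 1.16, adjusted p = 5.64e-05; adjusted p = 0.271 with an estimated correlation), with the hexokinase gene Hk2 at 3.15 ± 0.46. Skeletal muscle genes rose in 6 of 26 cases, or 11 adjusted over the list alone (median 1.86, adjusted p = 1.15e-05; adjusted p = 0.396 with an estimated correlation), with Mybpc2, a protein of fast muscle, at 3590 ± 449 against 248.1 ± 3.23 CPM. The muscle and adipocyte markers therefore moved with hydrogel at this day beside each of the other groups. The list of sugar and insulin signalling did not pass (adjusted p = 0.672), with a median of 0.30 and a mean of -0.02.

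At day 7, 3792 genes passed, 1734 higher and 2058 lower. Groups did not overlap in 70.2% of genes, where chance gives 10% if the libraries are separate samples. Lists passed in 29 of 44 cases, 12 up and 17 down, in 29 with the fry test and in 0 with an estimated correlation (7 at an unadjusted p below 0.05). With the 3 libraries of each day 7 group summed into 1, so that each group had 1 library and the spread came from the other days, edgeR called 0 genes (1347 at an unadjusted p below 0.05) and 28 lists. DESeq2 on the separate libraries called 4992 genes. With the muscle and adipocyte scores as covariates 8 genes and 13 lists passed, 51 of the 52 named genes were no longer past, and Hsd3b6, Hsd17b2, Tyr, Angptl8 and Cat turned in direction. Those covariates ended the list calls of collagen (adjusted p = 0.396), fibroblast (0.14), basal keratinocyte (0.228) and epidermal differentiation genes (0.152), and turned the wound-edge keratinocyte list downward (0.0146). Without 1 library the count was 1990, 1877 and 1943 for control day 7 replicates 1, 2 and 3, and 1859, 1954 and 1960 for hydrogel day 7 replicates 1, 2 and 3.

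At day 14, hair shaft keratins were higher and inflammatory and matrix genes lower with hydrogel (n = 3 per group). Krtap7-1, a keratin-associated protein of the hair shaft, stood at 50.2 ± 46.7 against 0.0916 ± 0.159 CPM (log2 fold change 8.94 ± 1.61, adjusted p = 0.00526), Gprc5d at 36.9 ± 30.8 against 0.234 ± 0.194 CPM, and Krt31 at 128 ± 109 against 1.06 ± 1.18 CPM (adjusted p = 0.00187). Krt33a, Krt81 and Krt83 rose as well, with log2 fold changes of 7.25 ± 1.28, 7.04 ± 1.28 and 7.04 ± 1.22, and belong to a family of near-identical hair keratins, so these are uncertain. Limma-voom with quality weights left these 6 genes short of its threshold, and so did the muscle and adipocyte covariates for Krtap7-1. Among genes that fell, Cxcl13, a B cell chemokine, stood at 0.336 ± 0.152 against 159 ± 268 CPM (-8.83 ± 1.75, adjusted p = 0.00504), where control day 14 replicate 1 held 468.5 CPM and the other 2 controls 4.41 and 3.71 CPM. Prg4, lubricin, stood at 0.992 ± 0.167 against 181 ± 298 CPM, again with 524.9 CPM in that library. Mrgprg fell by 8.54 on the log2 scale, but not without control day 14 replicate 1 (-2.51, adjusted p = 0.0778, with a range of 0.00132 to 0.0964 over all alternatives). Cxcl5, a neutrophil attractant, fell by 7.11 (SE 1.37). Saa3, higher with hydrogel at day 1, stood at 2.93 ± 0.89 against 341.1 ± 507.6 CPM (-6.86 ± 1.31, adjusted p = 0.00406). With only the 2 day 14 groups in the model none of these 5 lower genes passed, nor did Krtap7-1, Krt31, Krt33a, Krt81 and Krt83. Of the 45 named genes past at day 14, 21 lost their call in that model, among them also Mcm2, Mcm5, Mmp2, Mrc1, C1qc and Il1b.

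Collagen and matrix assembly genes fell in 21 of 24 cases at day 14, or 23 adjusted over the list alone, with a median of -2.78 (adjusted p = 5.21e-21; adjusted p = 0.108 with an estimated correlation). Col1a1 stood at 899.8 ± 177 against 7556 ± 4151 CPM (-3.07 ± 0.40, adjusted p = 0.000842), and Lum fell by 3.81 (SE 0.48) and Loxl2 by 2.53 (SE 0.32) on the log2 scale. Matrix proteases and inhibitors fell in 13 of 20 cases, or 15 adjusted over the list alone (median -2.45, adjusted p = 3.76e-13; adjusted p = 0.0955 with an estimated correlation), with the collagenase gene Mmp13 at -4.53 ± 0.57 and the gelatinase gene Mmp2 at -3.68 ± 0.52. Macrophage markers fell in 15 of 19 cases, or 18 adjusted over the list alone (median -3.93, adjusted p = 1.38e-15; adjusted p = 0.148 with an estimated correlation). Ms4a7 stood at 0.732 ± 0.396 against 26.4 ± 23.9 CPM. The lysosomal glycoprotein gene Cd68 (chromosome 11, 69664213 to 69666153, minus strand, GRCm38), a widely used macrophage marker, led the lysosome list at -3.90 ± 0.46 (adjusted p = 0.00069). That list fell in 7 of 22 cases, or 15 adjusted over the list alone (median -1.14, adjusted p = 4.62e-08; adjusted p = 0.163 with an estimated correlation). Both activation lists went down: of 14 classical (M1) genes 9 fell, or 13 adjusted over the list alone (adjusted p = 2.07e-09; adjusted p = 0.0955 with an estimated correlation), and of 16 alternative (M2) genes 10 fell, or 12 adjusted over the list alone (adjusted p = 4.46e-08; adjusted p = 0.131 with an estimated correlation). Cd80, a costimulatory ligand, stood at -2.95 ± 0.43 and the scavenger receptor Stab1 at -3.10 ± 0.40.

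Inflammatory cytokines and chemokines fell in 9 of 17 cases at day 14, or 11 adjusted over the list alone (median -2.44, adjusted p = 5.5e-06; adjusted p = 0.163 with an estimated correlation), led by the neutrophil attractant Cxcl2 at -5.38 ± 0.85. Neutrophil markers fell in 8 of 17 cases and 1 rose, or 10 fell and 1 rose adjusted over the list alone (adjusted p = 0.000148; adjusted p = 0.192 with an estimated correlation), with Csf3r at -4.72 ± 0.74. All 10 NADPH oxidase genes tested fell, over all genes and adjusted over the list alone (median -3.07, adjusted p = 5.45e-08; adjusted p = 0.163 with an estimated correlation), with Ncf4, a cytosolic subunit of the oxidase, at -3.09 ± 0.51. Interferon response genes fell in 12 of 19 cases, or 17 adjusted over the list alone (median -1.86, adjusted p = 4.45e-09; adjusted p = 0.214 with an estimated correlation). Endothelial genes fell in 13 of 23 cases, or 19 adjusted over the list alone (median -1.53, adjusted p = 2.99e-09; adjusted p = 0.169 with an estimated correlation), with Angpt2 at -2.25 ± 0.37. Of 6 lymphatic endothelium genes 4 fell, or 6 adjusted over the list alone (median -2.37, adjusted p = 1.53e-06; adjusted p = 0.0457 with an estimated correlation), with the hyaluronan receptor Lyve1 at -3.65 ± 0.51. The lists of T and NK cells (median -0.29, adjusted p = 0.378), B and plasma cells (-1.49, 0.127) and mast cells (-1.31, 0.201) did not pass. The macrophage, collagen and keratinocyte markers were those in which control day 14 replicate 1 stood apart.

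Cell cycle genes rose in 15 of 27 cases at day 14 and none of the 27 fell, or 25 rose adjusted over the list alone, with a median of 1.54 (adjusted p = 1.72e-13; adjusted p = 0.192 with an estimated correlation). The replication licensing genes Mcm2 and Mcm5 rose by 1.66 ± 0.31 and 2.15 ± 0.44, and both lost their call with only the day 14 groups in the model. Hair follicle genes rose in 12 of 25 cases, or 16 adjusted over the list alone (adjusted p = 3.79e-10; adjusted p = 0.163 with an estimated correlation). Their spread within groups was wide: Krt31 stood at 12.9, 141.6 and 228.6 CPM in the 3 hydrogel libraries and at 0, 0.857 and 2.34 CPM in the controls. Cholesterol synthesis genes rose in 5 of 19 cases, also adjusted over the list alone (median 1.12, adjusted p = 7.3e-07; adjusted p = 0.214 with an estimated correlation). Other tissue lists passed with few or no single genes past. The epidermal differentiation list (median 1.096, adjusted p = 0.000481; adjusted p = 0.461 with an estimated correlation) and the melanocyte list (median 2.03, adjusted p = 0.00241; adjusted p = 0.214 with an estimated correlation) moved upward, with 3 of 23 and 1 of 9 genes past. The skeletal muscle list moved downward (median -0.79, adjusted p = 0.0169; adjusted p = 0.605 with an estimated correlation) with 0 of 26 past, and did not pass without control day 14 replicate 2 (adjusted p = 0.0675) or 3 (0.063). Basal keratinocyte genes did not pass as a list (adjusted p = 0.0523), nor did adipocyte genes (0.623) or metallothioneins (0.0582). Nuclear-encoded oxidative phosphorylation genes did not pass either (0.794), with a median of -0.01 and a mean of 0.02.

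In total 2836 genes passed at day 14, 1025 higher and 1811 lower, and groups did not overlap in 43.7% of genes, where chance gives 10%. Lists passed in 30 of 44 cases, 6 up and 24 down, in 28 with the fry test, and 1 of them, lymphatic endothelium, also with an estimated correlation. The count was 433 with only these 2 groups in the model, 549 with the day 7 libraries summed, 4788 with the muscle and adipocyte scores as covariates and 5877 with limma-voom and quality weights. Without 1 library it was 1264 for control replicate 1, 4322 for control replicate 3, and 1876, 1022 and 806 for hydrogel replicates 1, 2 and 3. Of the collagen genes called lower, 16 of 21 stayed called without control day 14 replicate 1. Of the lists described above as passing at day 14 only skeletal muscle lost its call when 1 library was left out. Lists not described above also passed and lost their call without control day 14 replicate 1: erythrocyte (camera adjusted p = 0.165), peroxide and superoxide removal (0.157), Schwann cell (0.165) and sebocyte genes (0.513). Without control replicate 1 the medians of cholesterol synthesis, lysosome and NADPH oxidase genes were 0.67, -0.66 and -2, and without control replicate 3 that of epidermal differentiation was 1.76.

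**Figure D2:**
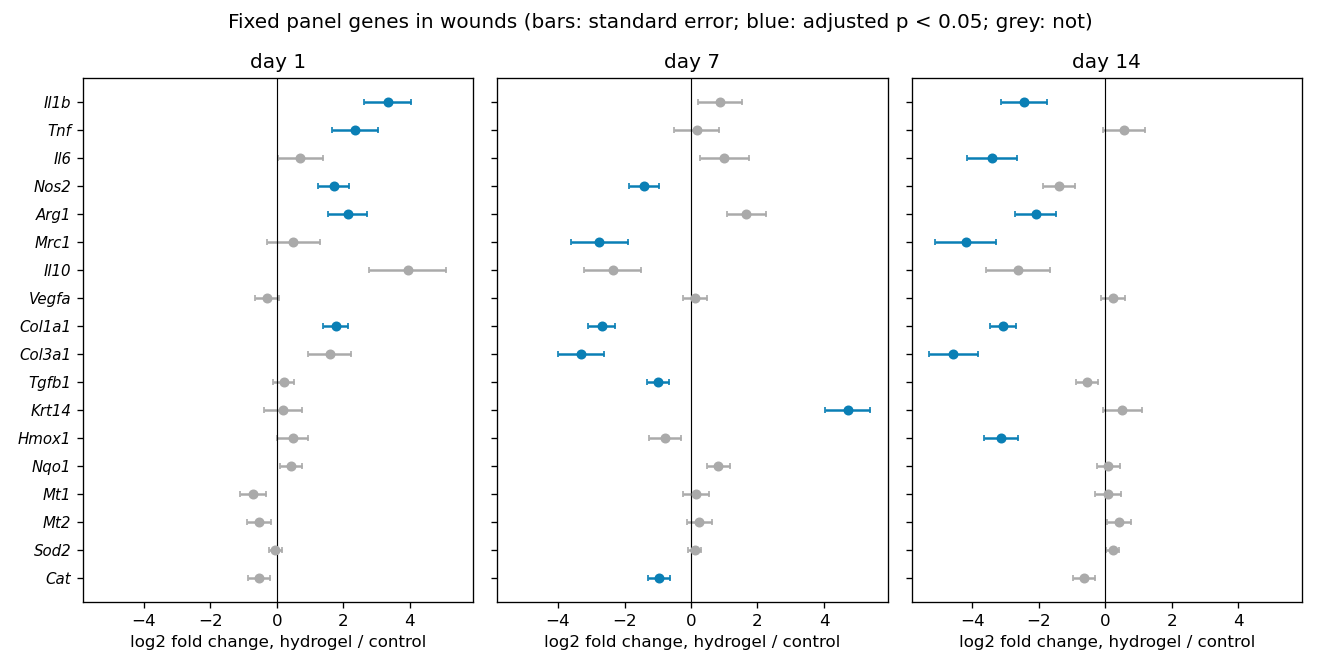
Log2 fold changes of hydrogel over control wounds for the 18 panel genes at days 1, 7 and 14 with standard errors, in blue where the adjusted p was below 0.05 and in grey where it was not. Il10 rests on 1 count in the controls at day 1 and on 3 counts in the hydrogel group at day 14.

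Calls at days 7 and 14, which share no library, overlapped chiefly among lower genes. Of 2058 genes lower at day 7 and 1811 lower at day 14, 844 were shared, where independent lists would share 212. Among higher genes 170 were shared against 101 for independent lists, and 32 were called in opposite directions. The log2 fold changes of days 7 and 14 correlated across genes at r = 0.47, those of days 1 and 7 at r = 0.08 and those of days 1 and 14 at r = -0.06, and genes are not independent replicates. Of genes called at days 1 and 7, 62 were higher at both (78.6 if independent), 129 lower at both (62.2 if independent) and 148 opposite.

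Averaged over the 3 days, 5594 genes passed, 2747 higher and 2847 lower (n = 9 per arm). Cell cycle genes rose in 24 of 27 cases, or 26 adjusted over the list alone (median 1.34, adjusted p = 8.78e-16; adjusted p = 0.189 with an estimated correlation), and collagen genes fell in 22 of 24, or 23 adjusted over the list alone (median -1.56, adjusted p = 1.29e-15; adjusted p = 0.189 with an estimated correlation). Macrophage markers fell in 17 of 19 cases, or 19 adjusted over the list alone (median -2.04, adjusted p = 1.75e-11; adjusted p = 0.189 with an estimated correlation), and cholesterol synthesis genes rose in 14 of 19, or 15 adjusted over the list alone (median 1.24, adjusted p = 7.45e-08; adjusted p = 0.212 with an estimated correlation). The cornified envelope gene Sprr2a3, of a family with near-identical members and therefore uncertain, had a log2 fold change of 4.51 ± 0.40 (adjusted p = 5.89e-05). Cxcl13 averaged -5.41 ± 0.87 and Gys2, the liver-type glycogen synthase, had -3.91 ± 0.69. Ucp1 averaged -4.34 ± 1.21 but was not past without control day 14 replicate 1 (adjusted p = 0.343, with a range of 4.53e-05 to 0.954 over all alternatives). With the day 7 libraries summed edgeR called 0 genes (3972 at an unadjusted p below 0.05) and 29 lists, with the tissue covariates it called 123 genes and 24 lists, without Cxcl13, Gys2 and Ucp1 among the genes and with medians of -0.54 for collagen and -0.84 for macrophage genes, and DESeq2 on all libraries called 6693 genes.

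The effect of hydrogel differed between days for 2785 of 17592 genes by the interaction test. Sdc4, a cell surface proteoglycan, had a log2 fold change of -1.56 at day 1, 1.56 at day 7 and 0.07 at day 14 (adjusted p = 0.000159). Rian, an imprinted noncoding RNA, went from 1.09 to -1.26 and -2.39 (adjusted p = 0.000159). The lysyl oxidase gene Loxl3 went from 1.61 to -1.90 and -2.37 (adjusted p = 0.000163), and the vascular collagen gene Col8a1 from 2.07 to -2.77 and -3.26 (adjusted p = 0.00019). For the collagen list the change in effect from day 1 to day 14 had an adjusted p of 3.24e-19 and for the macrophage list of 3.17e-16, and 0 of 44 lists passed with an estimated correlation (10 at an unadjusted p below 0.05). The count of genes was 27 with the day 7 libraries summed, and of the 10 named genes Fgd2, Lep and Sphk1 were then not past. It was 5295 without control day 1 replicate 1, 1686, 1619 and 1684 without control day 7 replicate 1, 2 or 3, 1805 and 1804 without hydrogel day 7 replicate 1 or 2, and 1718 and 1701 without hydrogel day 14 replicate 2 or 3.

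Control wounds changed between days 1 and 7 in 5553 genes, 2637 higher and 2916 lower. Among the genes that rose most, Chrng, the fetal acetylcholine receptor subunit, went from 0.0886 ± 0.0957 to 18.4 ± 1.54 CPM, Myh3, embryonic myosin, from 2.27 ± 3.05 to 374.6 ± 7.27 CPM, and Mymk, a myoblast fusion protein, from 0.114 ± 0.101 to 16.6 ± 0.56 CPM. Calcb was 213-fold lower at day 7 (59 to 1760) and Trim63, a ubiquitin ligase of muscle atrophy, fell by 7.54 on the log2 scale (SE 1.28), and both were not past with the day 7 libraries summed. Collagen genes rose in 18 of 24 cases, or 20 adjusted over the list alone (median 2.16, adjusted p = 1.72e-15; adjusted p = 0.143 with an estimated correlation), and macrophage markers in 14 of 19, or 15 adjusted over the list alone (median 2.64, adjusted p = 7.68e-08; adjusted p = 0.297 with an estimated correlation). Basal keratinocyte genes fell in 9 of 15, or 12 adjusted over the list alone (median -2.08, adjusted p = 1.05e-05; adjusted p = 0.297 with an estimated correlation). Between days 1 and 14, 5699 genes passed in control wounds, 2939 higher and 2760 lower. Collagen genes rose in 22 of 24 cases, also when adjusted over the list alone (median 3.22, adjusted p = 3.58e-22; adjusted p = 0.212 with an estimated correlation), and cell cycle genes in 26 of 27, or 27 adjusted over the list alone (median 3.60, adjusted p = 3.52e-19; adjusted p = 0.323 with an estimated correlation). Nuclear-encoded oxidative phosphorylation genes fell in 24 of 25, or 25 adjusted over the list alone (median -1.18, adjusted p = 2.87e-14; adjusted p = 0.285 with an estimated correlation). Adipocyte genes fell in 16 of 19, also adjusted over the list alone (median -3.46, adjusted p = 1.91e-08; adjusted p = 0.323 with an estimated correlation), with a median of -2.10 without control day 1 replicate 1. Both control libraries that stood apart in fat, muscle or epidermis were part of this comparison. Hair keratin Krt35 was at least 1090-fold and Krt73 at least 553-fold higher at day 14. Ucp1 fell by 9.50 on the log2 scale (SE 1.61), but not with limma-voom weights or with only these groups in the model, and Myh7, slow myosin, was 326-fold lower (112 to 1580), a change lost without control day 1 replicate 3 (-2.21, adjusted p = 0.299, the highest of a range from 1.57e-05). With the tissue covariates none of Krt35, Krt73, Ucp1 and Myh7 passed. In simulated data with each group's spread, 79.4% of the genes called between days 1 and 14 had not been changed (367 genes, in a simulation with 200 changed genes). That share is not an estimate for the 5699 real calls. The count of genes was 97 for day 7 and 2900 for day 14 with the day 7 libraries summed, 77 for day 14 with only these groups in the model, 604 with the tissue covariates, and 3765 without control day 1 replicate 2. For day 7 it was 3304 without that library and 3454, 3498 and 3505 without control day 7 replicate 1, 2 or 3.

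Hydrogel wounds changed in 3221 genes between days 1 and 7, 1366 higher and 1855 lower, and in 8415 between days 1 and 14, 3831 higher and 4584 lower. By day 7, Tyr was at least 180-fold and Chil4, a chitinase-like protein, at least 123-fold higher, the latter uncertain because of a near-identical neighbour. Neutrophil markers fell in 10 of 17 cases and 1 rose, or 14 fell and 2 rose adjusted over the list alone (median -2.98, adjusted p = 4.63e-06; adjusted p = 0.271 with an estimated correlation), and sebocyte genes rose in 10 of 14, or 11 adjusted over the list alone (median 3.56, adjusted p = 1.98e-07; adjusted p = 0.278 with an estimated correlation). By day 14, Krt73 was at least 6330-fold higher, Igfn1, a muscle protein, had gone from 1118 ± 1097 to 0.254 ± 0.072 CPM, and Retnlg, a neutrophil gene, was at least 612-fold lower. Cell cycle genes rose in 27 of 27 cases, also adjusted over the list alone (median 3.43, adjusted p = 4.04e-18; adjusted p = 0.268 with an estimated correlation), hair follicle genes in 24 of 25, likewise adjusted over the list alone (adjusted p = 4.58e-12; adjusted p = 0.268 with an estimated correlation), and skeletal muscle genes fell in 21 of 26, again also adjusted over the list alone (median -3.03, adjusted p = 3.37e-06; adjusted p = 0.472 with an estimated correlation). With the tissue covariates 1011 genes passed between days 1 and 14, Igfn1 not among them. With the day 7 libraries summed 1 gene passed between days 1 and 7, and neither Tyr nor Chil4 did. The day 7 count was 5169, 999 and 1620 without hydrogel day 1 replicate 1, 2 or 3, and 1155, 1020 and 1524 without hydrogel day 7 replicate 1, 2 or 3, and the lists past fell from 22 to 12 without hydrogel day 1 replicate 1.

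In RAW264.7 cells, interferon-induced and inflammatory genes were lower in the hydrogel group (n = 3 per group). Slamf7, a surface receptor of activated leukocytes, stood at 0.595 ± 0.150 against 21.3 ± 0.93 CPM, a log2 fold change of -5.12 ± 0.14 (adjusted p = 6.13e-09). Ifit1, an interferon-induced RNA-binding protein (chromosome 19, 34640871 to 34650009, plus strand, GRCm38), stood at 14.5 ± 0.36 against 96.2 ± 1.03 CPM (-2.73 ± 0.06, adjusted p = 3.62e-09), and Rsad2, the antiviral enzyme viperin, at 80.7 ± 11.1 against 843.3 ± 9.02 CPM (-3.38 ± 0.10). Il6 (chromosome 5, 30013114 to 30019981, plus strand) stood at 20.5 ± 1.36 against 135 ± 1.85 CPM (-2.72 ± 0.07, adjusted p = 3.62e-09). Trim30c, Gbp5 and Gbp2b also fell, by 4.90, 4.20 and 3.76 on the log2 scale, and are uncertain because their families hold near-identical members. Tnfsf15, a cytokine of the TNF family, had a log2 fold change of -3.65 ± 0.19. Klf2, a transcription factor that restrains inflammatory genes, rose by 2.52 ± 0.19 (adjusted p = 1.08e-06), Xirp1 by 2.50 ± 0.18, Dnph1 by 2.47 ± 0.18, the early response gene Fosb by 2.34 ± 0.13 and Ung, a uracil DNA glycosylase, by 2.31 ± 0.13.

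**Figure D3:**
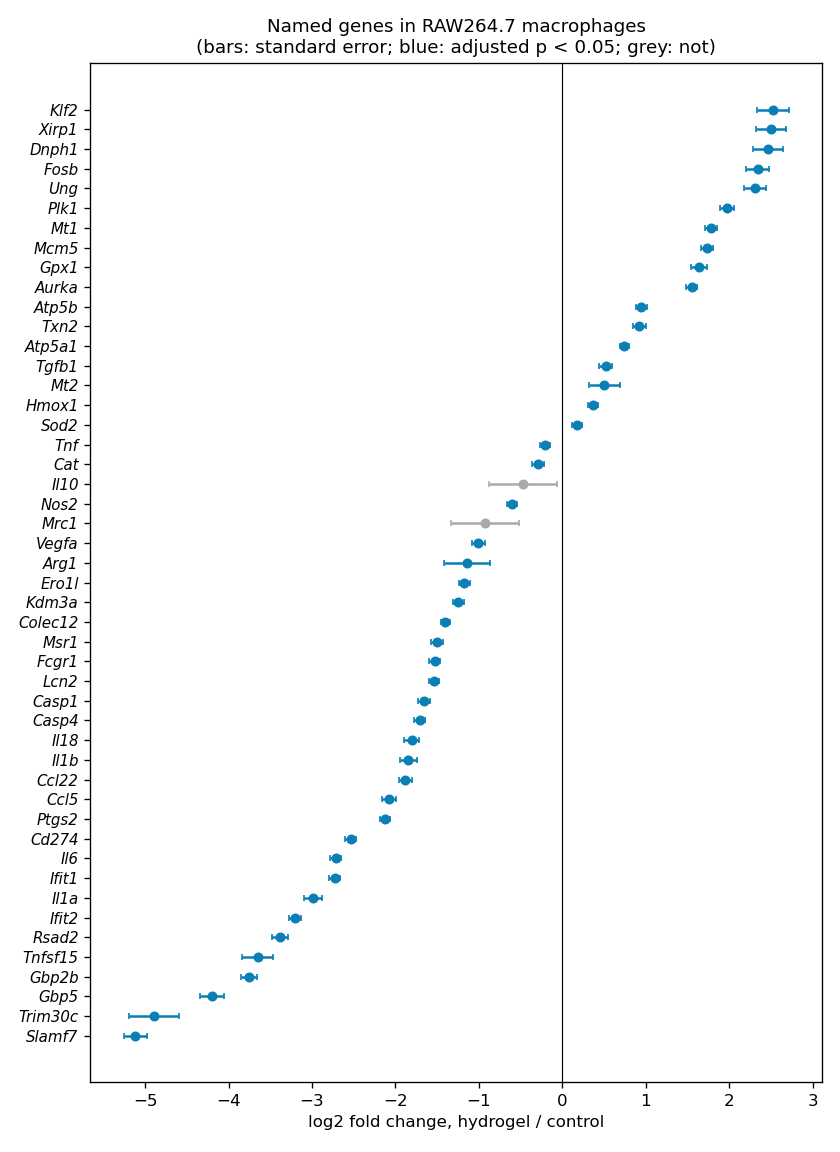
Log2 fold changes of hydrogel over control for the named genes in RAW264.7 cells with standard errors, ordered by size, in blue where the adjusted p was below 0.05 and in grey where it was not. Slamf7 lies lowest and Klf2 highest.

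Interferon response genes fell in 18 of 20 cases in the cells and 1 rose (median -1.44, adjusted p = 1.13e-17; adjusted p = 0.0161 with an estimated correlation). Ifit2, an interferon-induced gene like Ifit1, stood at -3.21 ± 0.08. Cell cycle genes rose in 22 of 27 and 2 fell (median 1.15, adjusted p = 2.28e-11; adjusted p = 0.0179 with an estimated correlation), with the mitotic kinase genes Aurka at 1.55 ± 0.07 and Plk1 at 1.98 ± 0.08 and Mcm5 at 1.73 ± 0.07. Nuclear-encoded oxidative phosphorylation genes rose in 21 of 25 and 1 fell (median 0.74, adjusted p = 1.07e-05; adjusted p = 0.138 with an estimated correlation), with the ATP synthase genes Atp5b at 0.95 ± 0.06 and Atp5a1 at 0.74 ± 0.06. Inflammatory cytokines and chemokines fell in 10 of 17 and 2 rose, or 4 rose adjusted over the list alone (median -0.43, adjusted p = 0.000107; adjusted p = 0.138 with an estimated correlation), with Il1a at -2.99 ± 0.11 and Ccl5 at -2.07 ± 0.08. Inflammasome genes fell in 8 of 14 and 2 rose (median -0.84, adjusted p = 0.000151; adjusted p = 0.085 with an estimated correlation), with Casp4, which senses intracellular LPS, at -1.71 ± 0.06 and Casp1 at -1.66 ± 0.07. Classical activation genes fell in 10 of 12 (median -0.97, adjusted p = 0.000529; adjusted p = 0.085 with an estimated correlation), among them the prostaglandin synthase gene Ptgs2 at 2937 ± 51.7 against 12860 ± 129 CPM. Alternative activation genes fell in 7 of 11 and 1 rose (median -0.83, adjusted p = 0.0486; adjusted p = 0.208 with an estimated correlation), a call lost with limma-voom weights (adjusted p = 0.0915), with the chemokine Ccl22 at -1.88 ± 0.08. Phagocytosis and scavenger receptor genes fell in 12 of 15 and 1 rose (median -1.40, adjusted p = 4.85e-05; adjusted p = 0.0758 with an estimated correlation), with Colec12 at -1.40 ± 0.06. For every other list counted here in the cells the numbers were the same when adjusted over the list alone.

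Genes of peroxide and superoxide removal rose in 9 of 15 cases and 1 fell (median 0.20, adjusted p = 0.0338; adjusted p = 0.33 with an estimated correlation). The median was 0.35 without hydrogel replicate 1 and 0.30 without control replicate 2. Gpx1, a glutathione peroxidase, had a log2 fold change of 1.64 ± 0.10 and Txn2, mitochondrial thioredoxin, of 0.92 ± 0.08. Hypoxia response genes fell in 12 of 18 and 4 rose (median -0.56, adjusted p = 0.0221; adjusted p = 0.392 with an estimated correlation). Of 7 metallothionein and metal response genes 4 rose and 2 fell, and the list did not pass (median 0.47, adjusted p = 1), while Mt1, a metal-binding metallothionein (chromosome 8, 94179082 to 94180327, plus strand, GRCm38), rose by 1.78 ± 0.07 (adjusted p = 3.82e-08), from 102 ± 1.01 to 351 ± 31.9 CPM. Macrophage identity markers went both ways, 7 higher and 5 lower of 14. Median and mean differed in sign for iron handling genes, which did not pass (0.20 and -0.15, adjusted p = 0.564). In all 9409 of 12972 genes passed, 4505 higher and 4904 lower, of which 2719 changed at least 2-fold, 1002 up and 1717 down. Groups did not overlap in 75.9% of genes, where chance gives 10%. Lists passed in 11 of 26 cases with camera and in 20 with the fry test, and 2 of the 11 passed with an estimated correlation. Genes called lower at day 14 in wounds and lower in the cells numbered 574, where independent lists would share 382, and those called higher in both 461 against 292. For day 7 they numbered 530 lower against 432 and 363 higher against 314. For day 1 they numbered 139 lower against 129, and 190 higher, fewer than the 213 of independent lists. Wound and cell log2 fold changes correlated across genes at r = -0.04, 0.13 and 0.23 for days 1, 7 and 14.

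The 18 genes of a panel fixed before the data were examined were read in every hydrogel comparison. At day 1, Il1b rose by 3.34 ± 0.71 on the log2 scale (adjusted p = 0.0141), Tnf by 2.36 ± 0.69 (0.0498), Nos2 by 1.71 ± 0.48 (0.041), Arg1 by 2.13 ± 0.59 (0.0409) and Col1a1 by 1.77 ± 0.38 (0.0146). Each of these 5 calls was lost without 1 library. For Il1b that was control day 1 replicate 2 (adjusted p = 0.0501), and for Col1a1 it was control replicate 2 (0.0507) or hydrogel replicate 3 (0.0533). Tnf lost it without control replicate 1 (0.102) or 2 (0.13) or hydrogel replicate 1 (0.0643) or 3 (0.163), Nos2 without control replicate 2 (0.0906) or 3 (0.0617) or hydrogel replicate 2 (0.0993) or 3 (0.0698), and Arg1 without control replicate 1 (0.085) or 2 (0.111) or hydrogel replicate 1 (0.0943) or 2 (0.0937). Over all alternatives the adjusted p ran from 3.8e-05 to 0.311 for Il1b, 0.00775 to 0.417 for Tnf, 0.00326 to 0.437 for Nos2, 0.0024 to 0.667 for Arg1 and 1.61e-05 to 0.304 for Col1a1. The highest for Arg1 came with limma-voom weights, where its direction turned. The others did not pass at day 1. Their log2 fold changes were 0.71 ± 0.67 for Il6, 0.50 ± 0.80 for Mrc1, -0.29 ± 0.36 for Vegfa, 1.595 ± 0.642 for Col3a1, 0.20 ± 0.33 for Tgfb1, 0.19 ± 0.58 for Krt14, 0.47 ± 0.48 for Hmox1, 0.42 ± 0.33 for Nqo1, -0.71 ± 0.39 for Mt1, -0.53 ± 0.36 for Mt2, -0.04 ± 0.19 for Sod2 and -0.54 ± 0.33 for Cat. Il10, with 1 count in the controls, was 20.4-fold higher (3.66 to 805, adjusted p = 0.051).

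At day 7 the panel had Krt14 higher and Col1a1 and Col3a1 lower, as above. Nos2 at -1.42 ± 0.46 (adjusted p = 0.0376), Mrc1, the mannose receptor of alternatively activated macrophages, at -2.76 ± 0.85 (0.032), Tgfb1 at -0.999 ± 0.329 (0.0419) and Cat, catalase, at -0.97 ± 0.33 (0.0457) also fell. Each of these 4 lost its call whichever of the 6 day 7 libraries was left out, at an adjusted p of 0.0786 to 0.123 for Nos2, 0.0678 to 0.097 for Mrc1, 0.087 to 0.112 for Tgfb1 and 0.102 to 0.124 for Cat. Over all alternatives the adjusted p ran from 1.94e-07 to 0.927 for Nos2, 4.26e-15 to 0.986 for Mrc1, 3.07e-09 to 0.773 for Tgfb1 and up to 0.781 for Cat. Not past at day 7 were Il1b at 0.88 ± 0.66, Tnf at 0.17 ± 0.68, Il6 at 1.01 ± 0.75, Arg1 at 1.66 ± 0.59, Il10 at -2.36 ± 0.85, Vegfa at 0.13 ± 0.36, Hmox1 at -0.78 ± 0.48, Nqo1 at 0.83 ± 0.34, Mt1 at 0.14 ± 0.39, Mt2 at 0.25 ± 0.37 and Sod2 at 0.11 ± 0.19. At day 14 Col1a1 and Col3a1 fell, the latter by 4.57 on the log2 scale (SE 0.73, adjusted p = 0.00187), as did Il6 at -3.42 ± 0.75 (0.00799), Mrc1 at -4.20 ± 0.91 (0.00769) and Hmox1, the haem-degrading oxygenase, at -3.14 ± 0.52 (0.00228). Il1b at -2.44 ± 0.69 (0.0274) lost its call without control day 14 replicate 2 (adjusted p = 0.123) or hydrogel day 14 replicate 1 (0.0832), 2 (0.0978) or 3 (0.0873), and over all alternatives its adjusted p ran from 0.000481 to 0.123. Arg1 at -2.10 ± 0.61 (0.0303) lost it without control replicate 1 (0.0607) or 2 (0.0681) or hydrogel replicate 1 (0.069), 2 (0.103) or 3 (0.116), within a range of 0.000909 to 0.116. Not past at day 14 were Tnf at 0.56 ± 0.62, Nos2 at -1.39 ± 0.47, Vegfa at 0.22 ± 0.36, Tgfb1 at -0.55 ± 0.33, Krt14 at 0.51 ± 0.58, Nqo1 at 0.10 ± 0.34, Mt1 at 0.09 ± 0.39, Mt2 at 0.41 ± 0.37, Sod2 at 0.22 ± 0.19 and Cat at -0.65 ± 0.33. Il10, with 3 counts in the hydrogel group, was 7.36-fold lower (2.52 to 35.7) and did not pass (adjusted p = 0.0748).

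Of the 14 panel genes tested in the RAW264.7 cells, Il1b stood at -1.84 ± 0.10 (adjusted p = 1.76e-07), Nos2 at -0.60 ± 0.06 (3.69e-06), Vegfa, an angiogenic growth factor, at -1.01 ± 0.08 (1.29e-06), Arg1 at -1.15 ± 0.28 (0.00344) and Cat at -0.29 ± 0.07 (0.00328), beside Il6 above. Tgfb1 rose by 0.52 ± 0.08 (0.000135) and Hmox1 by 0.37 ± 0.06 (0.000225), beside Mt1 above. Tnf at -0.21 ± 0.06 (0.00882) lost its call without control replicate 3 (adjusted p = 0.0605) or hydrogel replicate 2 (0.12). Mt2 at 0.50 ± 0.19 (0.0317) lost it without control replicate 1 (0.134) or 3 (0.0799) or hydrogel replicate 2 (0.0953), and Sod2 at 0.18 ± 0.06 (0.0147) without control replicate 1 (0.0794), 2 (0.0833) or 3 (0.0616). Over all alternatives the adjusted p ran from 8.19e-06 to 0.347 for Tnf, 0.00071 to 0.134 for Mt2 and 5.49e-06 to 0.0833 for Sod2. Mrc1 at -0.93 ± 0.41 (0.0614) and Il10 at -0.47 ± 0.41 (0.32) did not pass. Col1a1, Col3a1, Krt14 and Nqo1 had too few counts in the cells to be tested.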

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

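The tests of tissue amounts, of shared material, of a wrong day label and of the day 1 libraries that stand apart were chosen after the results had been seen, while the splits of the libraries and the test of the day 14 collagen genes were set beforehand.

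The effect of hydrogel differed between days for 2785 genes. By the interaction test the adjusted p was 0.000159 for Sdc4 and for Rian, 0.000163 for Loxl3, 0.00019 for Col8a1 and 0.00021 for each of Sphk1, Lep, Gadd45g, Castor2, Fgd2 and Cish. Lists that passed in opposite directions at days 1 and 7 were epidermal differentiation (adjusted p of the difference 6.03e-13), collagen and matrix assembly (3.05e-14), classical macrophage activation (7.02e-05), macrophage markers (2.37e-12) and NADPH oxidase (0.00051). At days 1 and 14 they were epidermal differentiation (6.18e-07), collagen (3.24e-19), cytokines and chemokines (1.04e-07), classical activation (4.6e-09), macrophage markers (3.17e-16), NADPH oxidase (2.84e-08), neutrophil markers (1.6e-07) and skeletal muscle (3.41e-05). At days 7 and 14 they were hypoxia response (1.32e-07), NF-kappaB feedback genes (1.62e-05) and skeletal muscle (1.17e-11). With an estimated correlation camera left 0 of 44 lists past in each of these contrasts (6, 10 and 7 at an unadjusted p below 0.05), and the fry test left 20, 18 and 7.

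Other splits of the same libraries were counted. For the average over the days 1 of 100 drawn splits, the real one, gave as many genes as its 5594, and the highest other gave 4271. For the interaction 2 of 100 gave as many as its 2785, and the highest other gave 4828. Both shares are under 0.05. If the libraries of every group are separate samples, chance in how they fell into groups was excluded at that level. This concerns only chance without a hydrogel effect at any day, and the labels name no animals. The splits mix the arms within a day and so do not test whether the effects are equal across days. The 6 other splits with the most interaction genes, 2087 to 4828, mixed the arms at only 1 or 2 of the days. The 10 splits of 3 libraries against 3 are too few for a share under 0.05. With that limit, 1 of 10 splits, the real one, gave as many genes in each of the others: day 1 (1329, highest other 1272), day 7 (3792, 0), day 14 (2836, 0), control day 7 against day 1 (5553, 0), control day 14 against day 1 (5699, 1753), hydrogel day 7 against day 1 (3221, 0), hydrogel day 14 against day 1 (8415, 0) and RAW264.7 cells (9409, 0).

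At day 7 collagen, macrophage and endothelial genes were lower and keratinocyte genes higher with hydrogel. A larger share of epidermis that dilutes every other tissue alike was excluded as the only change in these libraries. The lower quartile of the skeletal muscle list was 1.42 and the upper quartile of the collagen list -1.84. A larger share of epidermis beside different amounts of muscle was not tested. Different amounts of muscle and fat in the sampled pieces are a candidate explanation for much of the collagen change: with both scores as covariates its median was -0.379 instead of -2.11 (adjusted p = 0.396), because the estimates moved toward 0 and the median standard error grew from 0.528 to 0.789. The macrophage median went from -2.86 to -0.982 and the endothelial median from -1.63 to -0.932, while the median standard errors grew from 0.712 to 1.174 and from 0.447 to 0.857. Both lists still passed camera at its preset correlation (0.0163 and 0.0104), though with an estimated correlation neither had passed without covariates (0.282 for each), so muscle and fat may account for a part or for more. Whether the libraries of a day 7 group share 1 piece of tissue or 1 pool of RNA cannot be told apart from alike animals, as labels name no animals and the coefficient of variation was 4.68% and 11% there against 54.7% in day 1 controls.

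Control day 14 replicate 1 stood near the day 7 controls. Across genes it correlated with them at 0.943 to 0.944 and with the other day 14 controls at 0.895 and 0.868, and on the first principal component it lay at -78, the day 7 controls at -87.5 to -85.1 and the other day 14 controls at 50 and 79.3. A day 7 control library under a day 14 label cannot be told apart from a day 14 wound. Fat genes lay below the day 7 control mean in 19 of 19 cases with a median difference of -3.47, but the spread between day 1 controls allows a single library to differ by 7.094 in its mean over these genes, and the day 7 libraries may not be separate samples. That this library holds the lower collagen genes of day 14 was excluded, as 16 of 21 stayed called lower without it, with a list median of -2.11. A wound healed less far, or a sampled piece with less epidermis, stays open and was not tested.

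Across all genes the effects at day 1 and at the later days were hardly correlated (r = 0.08 and -0.06), and 8 lists passed in opposite directions at day 1 and at day 7 or 14. Control day 1 replicate 1 was not needed for these as a group at the preset correlation. Without it 7 of the 8 passed in their day 1 direction, and the median shrank more than 2-fold in only 1. Some of the 8 lists share members, and with an estimated correlation 0 of 44 lists had passed at day 1, so that count does not exclude this library as a source. Control day 1 replicate 1 is a candidate source for the skeletal muscle list. Its day 1 median went from 0.737 to 0.175 without that library (camera adjusted p = 0.838), while the median standard error went from 0.768 to 0.467. Whether the opposite directions rest on hydrogel day 1 replicate 1 cannot be told apart from a loss of libraries. Without it only 1 of the 8 lists passed at day 1, but the median shrank more than 2-fold in only 2 of them, and that of the macrophage list was 0.468 instead of 0.484 with a median standard error of 0.775 instead of 0.691. Without control day 1 replicate 2 or 3, 3 of the 8 passed. Without replicate 3 the epidermal differentiation median turned from -0.838 to 0.127 (camera adjusted p = 0.431). The collagen and macrophage medians were then 0.112 and 0.088 instead of 0.387 and 0.484. The interaction test had 27 genes with the day 7 libraries summed, which may come from their near-identity or from the loss of libraries.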

How the results depend on the processing

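The alternatives with day 7 libraries summed, with 2 control libraries left out and with tissue covariates were chosen after the results had been seen, and the others beforehand.

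The number of genes rested on how spread was estimated. With only the groups compared in the model edgeR called 0 genes at day 1 (1701 at an unadjusted p below 0.05), 11122 at day 7, 433 at day 14 and 77 between days 1 and 14 in controls. With day 7 libraries summed the counts were 14 at day 1, 0 at day 7 (1347 unadjusted), 549 at day 14, 0 for the average (3972 unadjusted), 27 for the interaction, 97 and 2900 for control days 7 and 14 against day 1, and 1 for hydrogel day 7 against day 1. Summing removes the day 7 replicates from the estimate of spread and leaves 1 library per day 7 group, and these effects were not separated. Without the 2 control libraries that stand apart, but with hydrogel day 1 replicate 1, they were 3564, 7149, 6729 for the interaction, 9393 for control day 7 and 6758 for hydrogel day 7 against day 1. With muscle and fat scores as covariates 2357 genes passed at day 1, 8 at day 7, 4788 at day 14, 123 for the average, 604 for control day 14 and 1011 for hydrogel day 14 against day 1, and 13 lists at day 7. Limma-voom with quality weights gave 4345, 12339 and 5877 at the 3 days, 8799 for the interaction, 10207 and 9229 for day 7 against day 1 in control and hydrogel wounds, and 13 lists for the latter. DESeq2 gave 2626 at day 1, 4992 at day 7, 6693 for the average and 4664 for the interaction. Without a filter on low counts 715 passed at day 1 and 2039 for hydrogel day 7 against day 1. A 2-fold minimum left 2642 genes for the average and 2719 in the cells. The cause of these shifts was otherwise not tested.

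With an estimated correlation camera left 0 lists at day 1, day 7, the average and each comparison between days (1, 7 and 11 at an unadjusted p below 0.05 for the first 3, and 6 to 9 for the others), 1 at day 14 and 2 in the cells. The fry test gave 0 at day 1 (10 unadjusted), 29 at day 7, 13 for hydrogel day 7 against day 1 and 20 in the cells. Leaving out 1 library gave 425 to 3012 genes at day 1, 1859 to 1990 at day 7, 806 to 4322 at day 14, 4304 to 7268 for the average, 1619 to 5295 for the interaction and 8615 to 9871 in the cells. Between days it gave 3304 to 7953 and 3765 to 6783 in controls, and 999 to 5169 and 6296 to 8890 in hydrogel wounds, for days 7 and 14. Lists past ran from 5 to 20 at day 1, 27 to 30 at day 7, 27 to 33 at day 14, 25 to 31 for the average, 11 to 12 in the cells, 24 to 26 and 18 to 22 in controls, and 12 to 23 and 24 to 28 in hydrogel wounds.

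Directions turned in few genes. With the covariates at day 7 they did so for Angptl8 (1.96, adjusted p = 0.543), Cat (0.50, 0.777), Hsd17b2 (-4.58, 0.705), Hsd3b6 (-5.58, 0.79) and Tyr (-17.74, 0.181), none of which passed. For Arg1 at day 1 limma-voom gave -0.38 (0.667). Of 2634 values of 261 named results under these settings, 2275 kept their call, 316 lost it, 37 gained one and 6 turned in direction. Sizes of change were not compared, and a result that passed in neither setting counted as kept.

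Residuals of equal replicate numbers did not correlate above 0.1 in every pair (0.37 to 0.09 at day 1, 0.03 to 0.09 at day 7, -0.02 to 0.24 at day 14). In the wounds most equal numbers still correlated more than unequal ones, such as 0.37 against at most -0.2 for day 1 replicate 1. Day 1 replicate 3 (0.09 against 0.23) and day 14 replicate 2 (-0.02 against 0.06) did not. Whether the numbers pair wound samples is therefore not settled. With the number as a block 1247, 4271 and 3056 genes passed at the 3 days and 9291 in the cells, and the calls of Arg1 (adjusted p = 0.0761), Tnf (0.052) and Trbc2 (0.0559) at day 1 and of Sod2 in cells (0.0518) ended.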

Other observations

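The tests of macrophage markers and of Mt1 in this part were chosen after the results had been seen.

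Pigment and gland genes also differed at day 7. Melanocyte genes rose in 7 of 9 cases (camera adjusted p = 6.5e-05; adjusted p = 0.282 with an estimated correlation), with Pmel, a melanosome protein gene, at 74.2 ± 1.24 against 0.983 ± 0.144 CPM. Sebocyte genes rose in 8 of 14 cases and 1 fell (median 4.08, adjusted p = 0.00035; adjusted p = 0.339 with an estimated correlation), with Acsbg1 at a log2 fold change of 5.75 ± 0.77 and Dgat2, which makes storage fat in adipocytes too, at -3.45 ± 0.62. Complement and coagulation genes fell in 11 of 19 cases at day 7 (median -1.90, adjusted p = 2.66e-05; adjusted p = 0.339 with an estimated correlation) and in 14 of 19 at day 14 (median -3.23, adjusted p = 4.46e-10; adjusted p = 0.163 with an estimated correlation), where the median was -1.72 without control day 14 replicate 1. C1qc, a macrophage-made complement gene, fell by 4.55 (SE 0.76) at day 14. With muscle and adipocyte scores as covariates the day 7 lists of melanocytes (turned downward, adjusted p = 0.333) and complement (0.521) no longer passed, and the sebocyte list did.

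Unfolded protein response genes fell in 3 of 18 cases at day 1 (median -0.47, adjusted p = 0.00334; adjusted p = 0.794 with an estimated correlation), a list call lost without hydrogel day 1 replicate 1 (adjusted p = 0.107), with a median of -0.26 without control day 1 replicate 1 and -0.73 without hydrogel day 1 replicate 2. In RAW264.7 cells genes of LPS tolerance and feedback inhibition fell in 7 of 18 cases and 2 rose (median -0.28, adjusted p = 0.0215; adjusted p = 0.138 with an estimated correlation), with Cd274, the checkpoint ligand PD-L1, at -2.54 ± 0.07, and the list did not pass with limma-voom weights (adjusted p = 0.186) and had a median of -0.14 without hydrogel replicate 1. Metallothionein genes did not pass as a list between hydrogel and control wounds at any day, while they moved downward from day 1 to day 7 in control (adjusted p = 0.0182) and hydrogel wounds (0.00524). With an estimated correlation 0 of 44 lists passed in either of these comparisons between days. The median in hydrogel wounds was -0.946 without hydrogel day 1 replicate 2, instead of -1.587.

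Macrophage markers fell in hydrogel wounds at day 14, which could come from fewer macrophages or from lower expression per macrophage. The change measured in RAW264.7 cells would not lower these markers as a group. The 11 markers that fell in the wounds and were tested in the cells had a median log2 fold change of 0.496 there, and 6 of the 11 were higher, among them Cd68, Lyz2 and Trem2. Fcgr3, Fcgr1, Itgam, Ccr2 and Adgre1 were lower in both. LPS in the treated cells is unsettled, so the cell difference may not be that of the hydrogel alone, and wound macrophages were not measured apart. A change per cell in the wounds therefore stays open for all 11. Fewer macrophages in the sampled tissue may also account for the fall, and cell counts in sections would test it.

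Mt1 rose in the cells by 1.78 on the log2 scale, as silver or another metal that enters cells might cause. A like rise in the wounds was excluded: the average over the 3 days was -0.161 with an upper 95% bound of 0.319. Differences in dose, in time after exposure or in the share of cells that meet the gel stay open, and measuring silver in both systems would test them. The labels leave LPS in the treated cells unsettled. Csf3, Cxcl2, Ccl3 and Tnf, which LPS induces, stood at like levels in both cell groups, Tnf a little lower with hydrogel. They were chosen after their values were seen, and Il1b, Il6 and Ptgs2 were lower with hydrogel, so these levels do not settle it. With no unstimulated library, and as a part of the gel could itself activate the cells, a share of LPS in the rise of Mt1 stays open.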
